A study of Mus musculus with 10 samples.

How the data were processed

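RNA from cultured mouse Wolffian ducts was measured on Affymetrix arrays. Per the labels' protocols, total RNA was extracted with a column kit, treated with DNase and accepted at an RNA integrity number of at least 7, and 100 ng per sample was labelled with biotin by the GeneChip WT Plus protocol. The deposited values are log2 signals, 1 for each of 22206 probe sets on each of 10 arrays. The log2 base was inferred from the range of the values (2.95 to 18.7), since the sources used here do not state it, and array quartiles were nearly equal (lower quartiles 5.06 to 5.29, upper quartiles 10.7 to 10.8), as in values already normalized between arrays. The summarization and normalization methods, their software, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Summarized array signals compress differences near their lower end, where a fold change understates the change in RNA.

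Groups came from the sample labels: 3 vehicle arrays (culture medium per the labels' protocols), 4 SAG arrays and 3 cyclopamine arrays. Replicates 1 to 3 carry the same numbers in each group. A table of the platform's annotation named 19572 probe sets with 1 gene symbol each, 0 with several, and left 2634 unnamed here; all 19572 gene identifiers were matched to a RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. All 22206 probe sets were tested, including 64 whose identifiers mark them as unmapped. For lists, each of 19505 genes was represented by the probe set with the highest mean signal (55 genes had several).

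Analysis used limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to the deposited log2 values of all 10 arrays (lmFit), which gives 7 residual degrees of freedom, and variances were moderated with eBayes (prior degrees of freedom 3.70). The contrasts were SAG against vehicle, cyclopamine against vehicle and SAG against cyclopamine, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Errors beside log2 changes are the moderated standard errors. No filter was applied. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 25 lists in each contrast, with camera at an estimated correlation and the rotation test fry as alternatives. The lists, written from textbook knowledge before the data were examined, cover the hedgehog pathway, sterol metabolism, signalling targets, stress responses, the cell cycle, cilia and markers of the tissues an explant could hold; 306 of 345 listed genes were measured under a name. With an estimated correlation, the hedgehog target, mesenchyme, smooth muscle and BMP and TGF-beta lists held their calls for cyclopamine against vehicle, the hedgehog target and mesenchyme lists for SAG against cyclopamine, and 0 lists for SAG against vehicle. By fry, which tests whether a list moves in a direction on balance and not against other genes, 2, 9 and 9 lists passed for SAG against vehicle, cyclopamine against vehicle and SAG against cyclopamine.

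The genes named were set by a rule fixed before the data were examined: core pathway genes in every contrast, the 8 largest rises and 8 largest falls among named, non-predicted genes that passed without overlap of the groups' arrays, and up to 4 members of each list described, by smallest p. Foxf1 and Crabp1 with cyclopamine, Cyp17a1, the genes given for both responses together other than core genes, and the genes of the added lists were chosen after their values were seen. For the shared vehicle arrays, unchanged groups without treatment effects were simulated 100 times from each probe set's residual variance.

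The scripts were tested on simulated data before use, with 200 of 22206 probe sets changed in each of 5 runs. For SAG against vehicle, 8.4% of changes of 0.5 log2 units were recovered, 58% of changes of 1 unit, 93.6% of changes of 2 and 100% of changes of 4. For cyclopamine against vehicle these shares were 6.8%, 51.6%, 93.6% and 99.6%, and for SAG against cyclopamine 7.2%, 58%, 92.8% and 98.8%. False calls made up 5.80%, 5.27% and 4.61% of calls for SAG against vehicle, cyclopamine against vehicle and SAG against cyclopamine. The simulated noise was independent between probe sets, so these shares do not cover deviations of an array shared by many probe sets. Recovery may also differ where many more than 200 probe sets change.

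Alternatives chosen before the data were examined were a further quantile normalization, centring each array on its median, leaving out the dimmest 25% of probe sets, fitting only the groups compared, an intensity-dependent prior variance, array weights, the replicate number as a block, unmoderated variances, other thresholds, the mean over a gene's probe sets, and leaving out each array in turn. Leaving out SAG replicate 1 and cyclopamine replicate 2 together, 9 further gene lists and further named genes were added after the values had been seen. Camera p-values of the added lists were adjusted in each contrast over the added lists tested by camera alone.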

Results

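Wolffian ducts, the embryonic tubes from which the epididymis and vas deferens form, were dissected from mouse embryos at 16.5 days post-coitum and kept in culture for 72 h before their RNA was measured on Affymetrix arrays. The labels' protocols describe Wolffian ducts, while the sample titles carry the word pronephros. The 10 arrays fall into 3 vehicle cultures, 4 cultures with 0.5 µM SAG and 3 cultures with 25 µM cyclopamine. SAG is an agonist of Smoothened that activates hedgehog signalling, and cyclopamine is a plant alkaloid that inhibits Smoothened. The series describes them as biological replicates. Whether the vehicle cultures received the solvent of the compounds is not given in the sources used here, so a change against vehicle may include the solvent. The Y-linked genes Eif2s3y (11.6 to 11.99 on the log2 scale), Kdm5d (9.19 to 9.95) and Uty (11.1 to 11.7) had signal on all 10 arrays. Array medians lay between 7.55 and 7.70, and the SD of log2 differences between arrays of a group was 0.35 to 0.60. The first principal component held 41.8% of the variance and placed the cyclopamine arrays at 49.0 to 59.7, the vehicle arrays at -9.74 to -5.18 and the SAG arrays at -37.3 to -33.9. The second held 16.6% and set cyclopamine replicate 2 (-51.7) apart from the other cyclopamine arrays (13.0 and 13.6). The number of arrays limits the precision of every value.

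Activation of the pathway with SAG was compared with vehicle first. Hhip, a membrane protein that binds hedgehog ligands and is itself a target of the pathway, rose by 4.55 ± 0.33 (SE) on the log2 scale, 23.4-fold (limma adjusted p = 0.000275). Ptch1, the hedgehog receptor, rose 2.94-fold (1.56 ± 0.22, limma adjusted p = 0.0120) and Gli1, a transcription factor induced by the pathway, 2.84-fold (1.51 ± 0.27, limma adjusted p = 0.0374). Foxf1, a mesenchymal forkhead factor, rose by 1.17 ± 0.21 (limma adjusted p = 0.0351). All 4 SAG arrays lay above all 3 vehicle arrays for each of these genes. The Gli1 call ended without vehicle replicate 2 (adjusted p = 0.204) or 3 (0.113), SAG replicate 1 (0.0708), 2 (0.0837), 3 (0.103) or 4 (0.0839), or cyclopamine replicate 3 (0.0530). The Foxf1 call ended without vehicle replicate 2 (adjusted p = 0.134) or 3 (0.0587), SAG replicate 1 (0.0690), 2 (0.0837), 3 (0.0753) or 4 (0.102), or cyclopamine replicate 1 (0.0504). Gli2 (0.55 ± 0.25), Smo (0.36 ± 0.21) and Gli3 (-0.19 ± 0.25) did not pass.

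**Figure D1:**
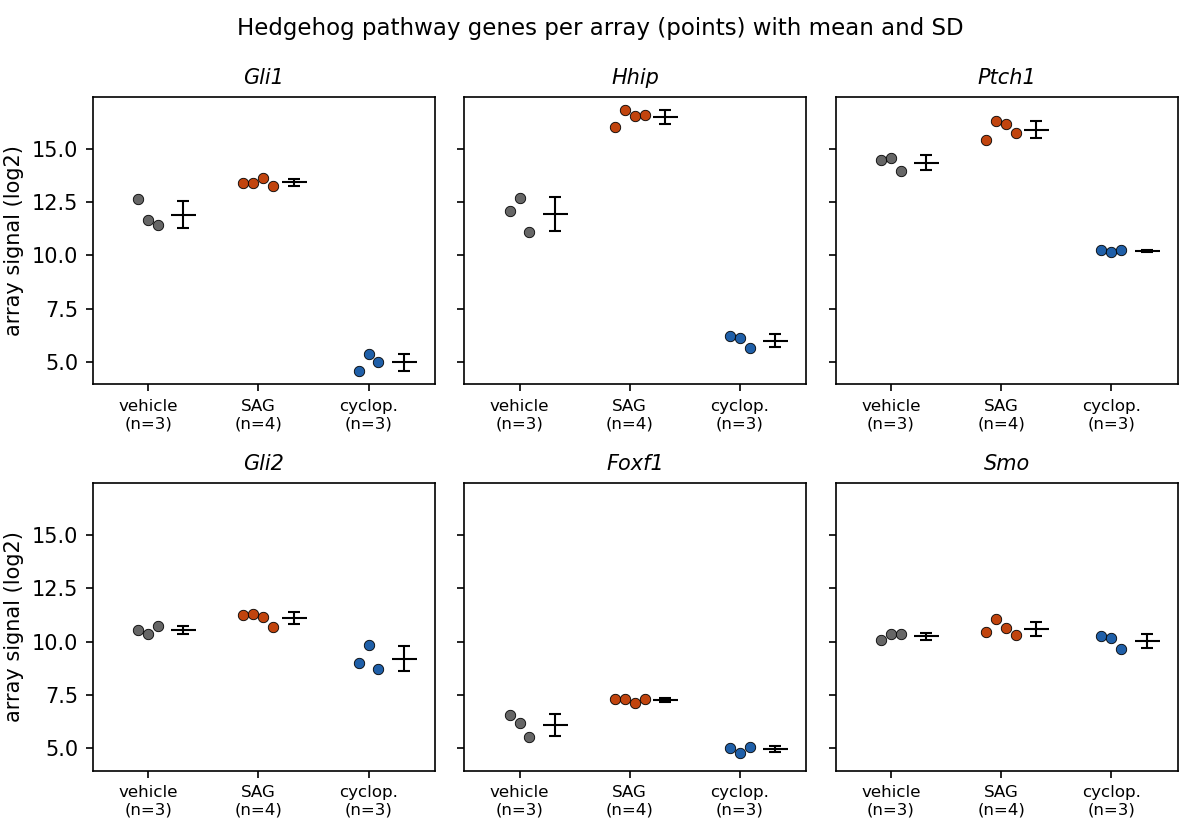
Array signal (log2) of Gli1, Hhip, Ptch1, Gli2, Foxf1 and Smo on every array of the vehicle (n = 3), SAG (n = 4) and cyclopamine (n = 3) groups, with the mean and SD beside the points. Mean Hhip signal was 16.5 with SAG, 11.9 with vehicle and 5.99 with cyclopamine.

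Of 10 measured hedgehog target genes, 4 rose with SAG, 0 fell and 6 did not pass, and 4 rose when adjusted over the list alone. The list mean was 0.84 and its median 0.28 (camera adjusted p = 0.000426; adjusted p = 0.189 with an estimated correlation). Among 20 measured ligands, receptors and transducers of the pathway, only Hhat, the acyltransferase that attaches palmitate to hedgehog ligands, rose (1.01 ± 0.17, limma adjusted p = 0.0256; 1 adjusted over the list alone). Shh itself was at -0.94 ± 0.33 and did not pass (limma adjusted p = 0.311).

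In all, 162 of 22206 probe sets changed with SAG, 100 higher (61.7%) and 62 lower, and 26 of them by more than 4-fold. The share of higher calls was 72.4% with each array centred on its median, 86.7% without vehicle replicate 2 and 51.0% with only the 2 groups in the fit. It was 48.1% without cyclopamine replicate 2, so the majority of rises varied in size and was lost without that array. A cyclopamine array enters this comparison only through the shared estimate of spread. Leaving it out altered which probe sets passed and left their log2 changes with SAG as they were. Higher with SAG were C1qtnf3, a secreted C1q-domain protein (3.66 ± 0.38, 12.6-fold), Meox2, a mesodermal homeobox factor (3.34 ± 0.49), Lepr, the leptin receptor (3.33 ± 0.36), and Zim1, an imprinted zinc finger gene (3.13 ± 0.54). Further rises were those of Sostdc1, a secreted antagonist of BMP and Wnt ligands (2.86 ± 0.30), the growth factor gene Fgf5 (2.83 ± 0.26) and Itgbl1 (2.71 ± 0.44). Lower with SAG were Sult1e1, the oestrogen sulfotransferase (-4.80 ± 0.87), Crabp1, a cytosolic retinoic acid-binding protein (-2.76 ± 0.15), Nmur2, a neuromedin U receptor (-2.48 ± 0.35), and Brinp3 (-2.41 ± 0.34). Further falls were those of Maob, monoamine oxidase B (-2.24 ± 0.25), Entpd1, an ectonucleotidase (-2.18 ± 0.41), Cpxm2 (-2.17 ± 0.40) and the kinesin gene Kif12 (-2.04 ± 0.38). Each had a limma adjusted p between 5.86e-05 and 0.0426 and no overlap between the arrays of the groups. Mean signal of Sult1e1 with SAG (4.55) and of Fgf5 with vehicle (4.75) lay below the lower quartile of probe set means (5.19), so these changes may be understated.

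Epithelial genes lay lower with SAG: all 16 measured members of the duct epithelium list had a negative change, with a mean of -1.05. The claudin gene Cldn7 (-1.56 ± 0.29) and Esrp1, an epithelial splicing factor (-1.40 ± 0.26), fell, 14 members did not pass, and 11 fell when adjusted over the list alone. Pax8 (-1.06 ± 0.22) and Cdh1, E-cadherin (-1.44 ± 0.31), were among those that did not pass (limma adjusted p = 0.0612 and 0.0717). The list passed camera (adjusted p = 1.50e-11; adjusted p = 0.189 with an estimated correlation). On SAG replicate 2 the list mean was -0.71, against -1.20 to -1.13 on the other SAG arrays. The Wnt target list was lower as well (mean -0.45, camera adjusted p = 0.00998; adjusted p = 0.490 with an estimated correlation). Axin2, a feedback inhibitor of the Wnt pathway, fell by 1.33 on the log2 scale (limma adjusted p = 0.0346), 8 of 9 members did not pass, and 2 fell when adjusted over the list alone. The call of the Wnt list was lost without vehicle replicate 1 (adjusted p = 0.106) or SAG replicate 1 (adjusted p = 0.0910).

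Smooth muscle genes had a mean change of -0.39 with SAG (camera adjusted p = 0.000866; adjusted p = 0.490 with an estimated correlation). None of the 15 members passed alone, the nearest being Synpo2 (-1.27 ± 0.25, limma adjusted p = 0.0506), and 5 fell when adjusted over the list alone. The hypoxia and glycolysis list was higher (mean 0.60, camera adjusted p = 3.37e-05; adjusted p = 0.500 with an estimated correlation), with 0 of 14 members past the test and 2 that rose when adjusted over the list alone. Vehicle replicate 3 had a list mean of -0.54, against 0.28 and 0.26 on the other vehicle arrays and 0.27 to 0.94 on the SAG arrays, and without it the change of the list was 0.33 (adjusted p = 0.0239). The vasodilator peptide gene Adm was at 1.57 ± 0.40. Genes of ER and amino acid stress were higher (mean 0.45, camera adjusted p = 0.00899; adjusted p = 0.512 with an estimated correlation), with Trib3 at 1.29 ± 0.48. None of the 15 members passed, also when adjusted over the list alone. That call was lost without vehicle replicate 1 (adjusted p = 0.113) or vehicle replicate 2 (mean 0.29, adjusted p = 0.107), and without vehicle replicate 3 the mean was 0.69. Genes of neurons and glia had a mean of -1.08 (camera adjusted p = 0.0329; adjusted p = 0.653 with an estimated correlation), and 0 of 8 members passed, also when adjusted over the list alone. The call was lost without vehicle replicate 1 (adjusted p = 0.201), vehicle replicate 2 (adjusted p = 0.133) or SAG replicate 4 (adjusted p = 0.131). This list varied within every group, from -1.01 to 0.58 on the vehicle arrays, -2.04 to -0.42 on the SAG arrays and -1.66 to 0.30 on the cyclopamine arrays. The remaining lists did not pass (camera adjusted p from 0.0912 to 0.930), among them mesenchyme and fibroblasts (mean 0.22, adjusted p = 0.0932), in which 3 members rose and 1 fell when adjusted over the list alone. Mean, median and test differed in sign for the BMP and TGF-beta, endothelium, kidney, growth factor and hedgehog ligand and receptor lists, which did not pass.

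The SAG count of 162 was 69, 45 and 77 without vehicle replicate 1, 2 or 3, then 93, 71 and 78 without SAG replicate 2, 3 or 4, and 339 without cyclopamine replicate 2. It was 311 without both SAG replicate 1 and cyclopamine replicate 2, and 9 with unmoderated variances. The count of risen hedgehog targets was 2 without vehicle replicate 2 or 3 or any SAG array, and that of fallen duct epithelium genes was 0 without vehicle replicate 1, 2 or 3 or SAG replicate 1, 3 or 4, 1 without cyclopamine replicate 1 and 6 without cyclopamine replicate 2. Of the 23 named genes that passed, Hhip, Ptch1, Crabp1, Maob, Fgf5, C1qtnf3, Sostdc1 and Lepr passed with any single array left out. Beside Gli1 and Foxf1, the calls of Sult1e1, Cpxm2, Entpd1, Kif12, Cldn7 and Esrp1 ended in 7 of the 10 left-out arrays, those of Itgbl1, Zim1 and Axin2 in 6, that of Hhat in 5 and those of Brinp3, Nmur2 and Meox2 in 2 (highest adjusted p 0.220, for Entpd1 and Kif12 without vehicle replicate 2). Leaving out vehicle replicate 1, 2 or 3 ended 9, 15 and 15 calls, SAG replicate 1, 2, 3 or 4 ended 8, 9, 12 and 12, and cyclopamine replicate 1 or 3 ended 4 and 1.

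Inhibition of the pathway with cyclopamine gave the opposite direction at Gli1, Hhip and Ptch1. Gli1 fell by 6.93 on the log2 scale (SE 0.29, 122-fold, limma adjusted p = 1.57e-06). Hhip (-5.95 ± 0.35, 61.8-fold lower) and Ptch1 (-4.12 ± 0.24, 17.4-fold lower) fell as well. Gli2 fell by 1.36 on the log2 scale (SE 0.27, limma adjusted p = 0.0177), while Smo (-0.22 ± 0.22) and Gli3 (-0.13 ± 0.27) did not pass. The Gli2 call ended without vehicle replicate 1 (adjusted p = 0.0654) or 3 (0.0637) or cyclopamine replicate 1 (0.0580) or 3 (0.0545). Mean signal with cyclopamine was 4.98 for Gli1 and 4.96 for Foxf1, below the lower quartile of probe set means (5.19), so their falls may be understated. Of the 10 hedgehog targets, 5 fell, 0 rose and 5 did not pass, with Bcl2, an inhibitor of apoptosis (-1.28 ± 0.20), and Foxf1 (-1.12) among those that fell. Adjusted over the list alone, 6 fell. The list mean was -2.20 and its median -1.06 (camera adjusted p = 4.57e-09, and 0.0168 with an estimated correlation).

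Among contractile genes, 11 of 15 smooth muscle genes fell, 4 did not pass, and 13 fell when adjusted over the list alone (mean -2.24, camera adjusted p = 1.16e-19; adjusted p = 0.0168 with an estimated correlation). Actg2, enteric gamma actin, fell by 5.54 on the log2 scale (46.5-fold), and Cnn1, calponin, was 32.9-fold lower (-5.04 ± 0.20). Myh11, smooth muscle myosin heavy chain (-3.62 ± 0.28), Myl9, a myosin light chain (-2.99 ± 0.17), and Acta2, smooth muscle alpha actin (-2.32 ± 0.14), fell as well. Genes of mesenchyme and fibroblasts fell in 6 of 15 cases, 9 when adjusted over the list alone (mean -0.68, camera adjusted p = 1.80e-05; adjusted p = 0.0168 with an estimated correlation). Those that fell included Inhba, an activin subunit (-3.40 ± 0.34), Twist2 (-2.43 ± 0.25), Postn, periostin (-2.04 ± 0.37), and the collagen gene Col1a1 (-0.76 ± 0.14). BMP and TGF-beta targets had a mean of -0.67 (camera adjusted p = 0.000711; adjusted p = 0.0450 with an estimated correlation): Bmp4 (-2.07 ± 0.33) and Ccn2 (-1.21 ± 0.28) fell, 8 did not pass, and 6 fell when adjusted over the list alone. The Ccn2 call ended without vehicle replicate 1, 2 or 3, SAG replicate 3 or 4, or cyclopamine replicate 2 or 3 (adjusted p 0.0542 to 0.117).

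**Figure D2:**
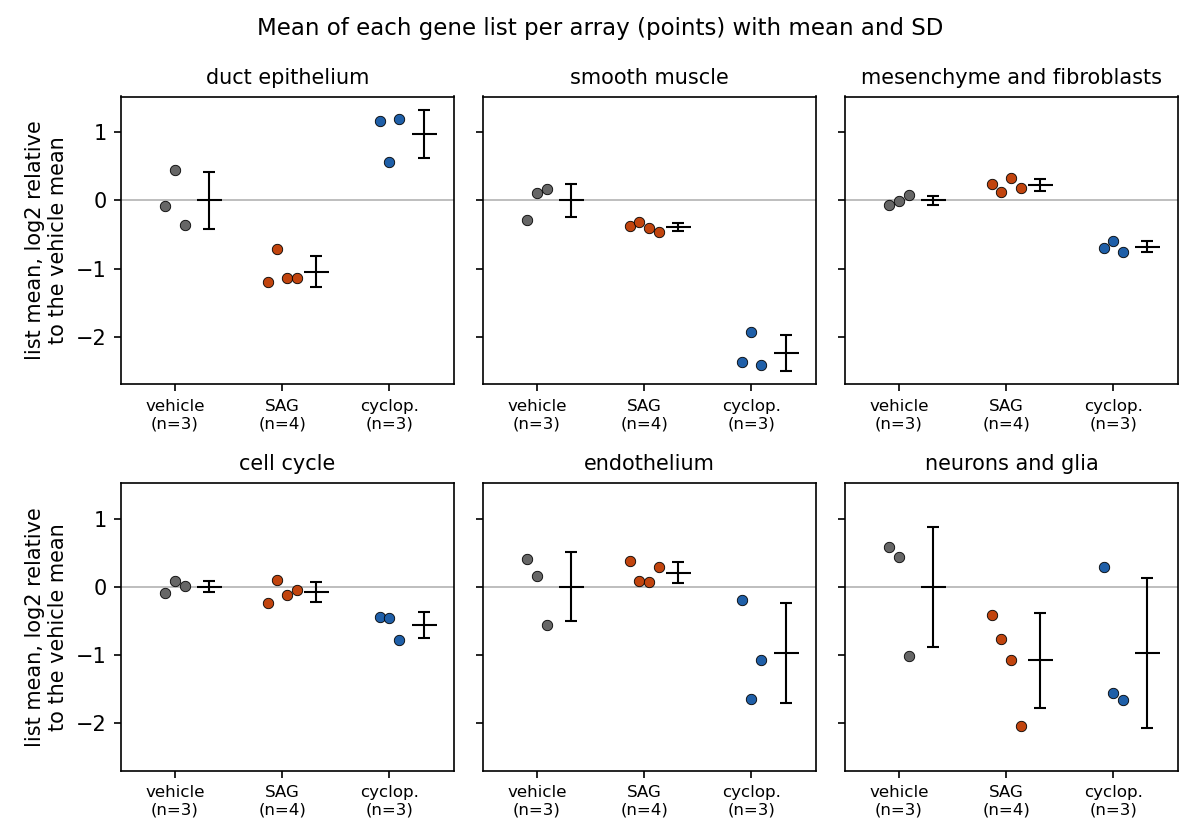
Mean of 6 gene lists on each array (log2 relative to the vehicle mean) for vehicle (n = 3), SAG (n = 4) and cyclopamine (n = 3), with the group mean and SD beside the points. The smooth muscle mean lay between -2.41 and -1.93 on the cyclopamine arrays and between -0.46 and -0.32 on the SAG arrays, and the duct epithelium mean between 0.57 and 1.20 with cyclopamine and between -1.20 and -0.71 with SAG.

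Duct epithelium genes rose with cyclopamine in 7 of 16 cases, 9 did not pass, and 12 rose and 1 fell when adjusted over the list alone (mean 0.98, camera adjusted p = 1.66e-06; adjusted p = 0.201 with an estimated correlation). Pax2 (3.48 ± 0.45, 11.1-fold) and Pax8 (1.34 ± 0.23), transcription factors of the nephric lineage, and the tight junction genes Cldn4 (2.37 ± 0.44) and Cldn3 (1.81 ± 0.43) were among them. The Cldn3 call ended without vehicle replicate 1 or 3, SAG replicate 3 or 4, or cyclopamine replicate 1 or 3 (adjusted p 0.0567 to 0.118), and the Cldn4 call without vehicle replicate 1 (0.0540) or 3 (0.0523). Cell cycle genes were lower: 5 of 19 fell, 14 did not pass, and 11 fell when adjusted over the list alone (mean -0.56, camera adjusted p = 9.96e-09; adjusted p = 0.201 with an estimated correlation). Ccna2, cyclin A2, fell (-1.73 ± 0.28), as did E2f1 (-0.99 ± 0.15) and the replication helicase genes Mcm5 (-0.82 ± 0.15) and Mcm6 (-0.52 ± 0.13). The Mcm6 call ended with any array but SAG replicate 1 left out (adjusted p 0.0508 to 0.127), and the Mcm5 call without vehicle replicate 3 (0.0546). In the endothelium list Kdr, a VEGF receptor, fell (-1.44 ± 0.31), 10 of 11 members did not pass, and 2 fell when adjusted over the list alone (mean -0.97, camera adjusted p = 0.00219; adjusted p = 0.295 with an estimated correlation). The Kdr call ended without vehicle replicate 1, 2 or 3 or cyclopamine replicate 1 or 3 (adjusted p 0.0612 to 0.103), and without cyclopamine replicate 2 the mean of the list endothelium, cyclopamine vs vehicle, was -0.63.

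With cyclopamine, itself a steroidal alkaloid, none of 19 genes of cholesterol synthesis and uptake passed alone or when adjusted over the list alone, with Cyp51, lanosterol demethylase, at 0.39 ± 0.13 and a list mean of 0.22 (camera adjusted p = 0.0139; adjusted p = 0.657 with an estimated correlation). The call was lost without vehicle replicate 1 (adjusted p = 0.0530), vehicle replicate 3 (adjusted p = 0.0553) or cyclopamine replicate 2 (mean 0.15, adjusted p = 0.127). None of 8 targets of the sterol-sensing receptor LXR passed alone, 4 rose when adjusted over the list alone, and the cholesterol exporter gene Abca1 was at 0.70 ± 0.19 (list mean 0.38, camera adjusted p = 0.0196; adjusted p = 0.201 with an estimated correlation). That call was lost without vehicle replicate 3 (adjusted p = 0.0553) or cyclopamine replicate 1 (adjusted p = 0.0587). The remaining lists did not pass (camera adjusted p from 0.0966 to 0.931). Mean, median and test differed in sign for the Wnt target, growth factor and adipocyte lists among them.

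Across the array, 1136 probe sets changed with cyclopamine, 482 higher (42.4%) and 654 lower, 142 of them by more than 4-fold. The share of higher calls was 50% with each array centred on its median, which ended the excess of falls, and 45.7% with quantile normalization again. It was 35.0% with only the 2 groups in the fit, and 31.5% and 32.6% without vehicle replicate 1 or 3, where the excess was larger. Beyond the genes above, the largest falls were those of Ajap1, an adherens junction protein (-5.03 ± 0.68), Npy1r, a neuropeptide Y receptor (-4.49 ± 0.83), the potassium channel gene Kcnd3 (-4.46 ± 0.26) and Chrdl1, a BMP antagonist (-4.43 ± 0.59). The largest rises were those of the urea transporter gene Slc14a2 (32.0-fold), the chemokine genes Ccl6 (4.96 ± 1.14), Ccl9 (4.30 ± 0.88) and Ccl3 (4.13 ± 0.93), and Mmp12, macrophage elastase (4.92 ± 1.09). Others were those of Cpn1, carboxypeptidase N (4.48 ± 0.44), Atp6v0d2, a proton pump subunit (3.88 ± 0.55), and Fxyd2, a regulator of the sodium pump (3.61 ± 0.27). Each had a limma adjusted p of 0.0334 or lower and no overlap between the arrays of the groups. The macrophage and leukocyte list did not pass (mean 0.34, camera adjusted p = 0.116). Its mean was 1.11 on cyclopamine replicate 1, against -0.13 and 0.06 on the other cyclopamine arrays. For the list macrophages and other leukocytes, cyclopamine vs vehicle, the mean was -0.04 without that array (adjusted p = 0.987), and the list passed without cyclopamine replicate 2 (0.58, adjusted p = 0.0185) or 3 (0.49, adjusted p = 0.0281). Cd14 (2.33 ± 0.40) and Fcer1g (1.41 ± 0.28) rose, 11 of 13 members did not pass, and 5 rose and 2 fell when adjusted over the list alone. The Fcer1g call ended without vehicle replicate 2 (adjusted p = 0.0650) or vehicle replicate 3 (adjusted p = 0.0606).

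The cyclopamine count of 1136 was 485, 580 and 625 without vehicle replicate 1, 2 or 3 and 698 and 679 without cyclopamine replicate 1 or 3, and 1591 without both SAG replicate 1 and cyclopamine replicate 2. The count of risen duct epithelium genes was 2 without vehicle replicate 1, 3 without vehicle replicate 3, SAG replicate 3 or 4 or cyclopamine replicate 1, 4 without cyclopamine replicate 3 and 11 without cyclopamine replicate 2. That of fallen cell cycle genes was 2 without vehicle replicate 3 and 3 without vehicle replicate 1 or 2, SAG replicate 2, 3 or 4 or cyclopamine replicate 3, and that of fallen endothelial genes 0 without vehicle replicate 1, 2 or 3 or cyclopamine replicate 3 and 3 without cyclopamine replicate 2. Without SAG replicate 1, 4 leukocyte genes rose. Of the 37 named genes that passed, 24 passed with any single array left out. Leaving out vehicle replicate 1, 2 or 3 ended 12, 8 and 10 calls, cyclopamine replicate 1, 2 or 3 ended 8, 4 and 6, and SAG replicate 2, 3 or 4 ended 1, 3 and 3. The calls of Ccl3, Ccl6 and Mmp12 each ended in 5 of the 10 left-out arrays, with the highest adjusted p without vehicle replicate 2 (0.112, 0.118 and 0.0998), that of Ccl9 in 3 (up to 0.0707), that of Slc14a2 without vehicle replicate 1 (0.0510) or 2 (0.0631) and that of Npy1r without vehicle replicate 1 (0.0524).

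SAG was also set directly against cyclopamine, the widest contrast of pathway activity. Hhip was 10.50 ± 0.33 higher on the log2 scale, Gli1 8.44 ± 0.27, Ptch1 5.68 ± 0.22 and Gli2 1.91 ± 0.25 (limma adjusted p = 9.73e-08, 9.73e-08, 2.75e-07 and 0.000696), while Smo (0.59 ± 0.21) and Gli3 (-0.05 ± 0.25) did not pass. The hedgehog target list had a mean of 3.04 and a median of 1.09 (camera adjusted p = 4.76e-09, and 0.0186 with an estimated correlation). Of its 10 members 5 were higher, 8 when adjusted over the list alone. Among ligands, receptors and transducers, Hhat (1.45 ± 0.17) and the co-receptor gene Boc (1.18 ± 0.24) were higher and the co-receptor gene Cdon (-0.95 ± 0.19) lower. Of 20 members 3 were higher and 3 lower, 6 and 4 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.515). Outside the pathway the largest differences were at Ajap1 (6.43 ± 0.63), Chrdl1 (5.66 ± 0.55), Itgbl1 (5.36 ± 0.44), Wfdc1 (5.18 ± 0.25) and Ntrk3, the neurotrophin-3 receptor (5.15 ± 0.40), higher with SAG. Lower with SAG were Sult1e1 (-5.90 ± 0.87), Cpn1 (-5.22 ± 0.41), Pax2 (-5.21 ± 0.42), Slc14a2 (-5.06 ± 0.91) and Spink8 (-4.91 ± 0.56), followed by Mmp12 (-4.81 ± 1.02), Ccl3 (-4.78 ± 0.87) and Hp, haptoglobin (-4.56 ± 1.08). Mean signal with SAG of Sult1e1 (4.55), Cpn1 (4.83) and Hp (5.12) and with cyclopamine of Gli1 (4.98) and of Myocd (4.84), a smooth muscle gene, lay below the lower quartile of probe set means (5.19), so these differences may be understated.

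In this contrast 12 of 16 duct epithelium genes were lower with SAG, also when adjusted over the list alone (mean -2.02, camera adjusted p = 2.52e-12; adjusted p = 0.0815 with an estimated correlation). Among them were Pax8 (-2.39 ± 0.22), Esrp1 (-2.48 ± 0.26) and Cldn4 (-3.66 ± 0.41). Smooth muscle genes were higher in 10 of 15 cases, with 11 higher and 1 lower when adjusted over the list alone (mean 1.85, camera adjusted p = 2.46e-11; adjusted p = 0.0758 with an estimated correlation). They included Cnn1 (4.43 ± 0.19) and Myocd, the coactivator of the smooth muscle programme (3.97 ± 0.33). Mesenchymal genes were higher in 10 cases and lower in 1 (mean 0.90, camera adjusted p = 1.23e-05; adjusted p = 0.0186 with an estimated correlation). Inhba was at 4.39 ± 0.32 and Postn at 3.33 ± 0.34, and 10 were higher and 3 lower when adjusted over the list alone. Cell cycle genes were higher in 7 of 19 cases, 11 when adjusted over the list alone (mean 0.48, camera adjusted p = 1.23e-05; adjusted p = 0.340 with an estimated correlation). They included E2f1 (1.15 ± 0.14) and Top2a (0.76 ± 0.17). Endothelial genes were higher in 5 of 11 cases, 6 when adjusted over the list alone (mean 1.18, camera adjusted p = 0.00215; adjusted p = 0.340 with an estimated correlation). They included Cdh5, VE-cadherin (3.94 ± 1.00), and Kdr (1.23 ± 0.29). BMP and TGF-beta targets were higher in 5 of 10 cases and lower in 1, with 6 and 2 when adjusted over the list alone (mean 0.64, camera adjusted p = 0.00673; adjusted p = 0.0967 with an estimated correlation). Bmp4 was higher (2.38 ± 0.31) and the BMP antagonist gene Nog lower (-1.06 ± 0.23). LXR targets were lower in 3 of 8 cases, 6 when adjusted over the list alone (mean -0.53, camera adjusted p = 0.00342; adjusted p = 0.109 with an estimated correlation), with Abca1 at -0.90 ± 0.18. In the hypoxia and glycolysis list only Adm was higher (1.88 ± 0.40), 3 when adjusted over the list alone (mean 0.62, camera adjusted p = 0.00212; adjusted p = 0.525 with an estimated correlation). The gonad list had a mean of 0.53, carried by SAG replicate 1 (1.45 relative to vehicle, against -0.16 to 0.15 on the other SAG arrays), with 0 of 11 members past the test, also when adjusted over the list alone (camera adjusted p = 0.0456; adjusted p = 0.634 with an estimated correlation). Its call was lost without SAG replicate 1 (mean 0.16, adjusted p = 0.471), vehicle replicate 1 (adjusted p = 0.0501), cyclopamine replicate 1 (adjusted p = 0.139) or cyclopamine replicate 3 (adjusted p = 0.0848). On SAG replicate 1 the steroid enzyme gene Cyp17a1, named after its values were seen, was at 8.03, against at most 4.45 on any other array. The remaining lists did not pass (camera adjusted p from 0.109 to 0.988). Mean, median and test differed in sign for the growth factor, p53 target and neuron lists among them.

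Altogether 2518 probe sets differed between SAG and cyclopamine, 1203 higher (47.8%) and 1315 lower with SAG. The share of higher calls was 54.2% with each array centred on its median and 50.3% with quantile normalization again, so the majority direction turned with the scaling. Of the 48 named genes that passed, 40 passed with any single array left out, and Hp, Top2a, Aurkb, Kdr, Cdh5, Emcn, Flt1 and Adm did not (highest adjusted p 0.130, for Flt1). The count of higher cell cycle genes was 2 without SAG replicate 2 or cyclopamine replicate 3, 3 without SAG replicate 3 or 4 and 4 without vehicle replicate 1 or 3. That of endothelial genes was 0 without SAG replicate 2 or 4, 1 without SAG replicate 1 or 3 or cyclopamine replicate 3 and 3 without vehicle replicate 1 or 2 or cyclopamine replicate 1. Without cyclopamine replicate 3, 3 BMP and TGF-beta targets were higher and 5 LXR targets lower. Lower mesenchymal genes numbered 2 without SAG replicate 1 or 3 or cyclopamine replicate 2. Higher genes of the hypoxia list numbered 0 without cyclopamine replicate 1, 2 without vehicle replicate 1 or 3, SAG replicate 2 or cyclopamine replicate 3 and 3 without cyclopamine replicate 2, and lower hedgehog ligand and receptor genes 1 without SAG replicate 3 or 4 or cyclopamine replicate 1. Leaving out SAG replicate 1, 2, 3 or 4 ended 3, 7, 5 and 5 calls, cyclopamine replicate 1, 2 or 3 ended 4, 1 and 5, and vehicle replicate 1 or 2 ended 1 each.

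The responses to SAG and to cyclopamine were then compared gene by gene, each against the same 3 vehicle arrays. Of the 64 probe sets that changed in both comparisons, 40 were higher with SAG and lower with cyclopamine, Hhip, Ptch1, Gli1, Foxf1 and Itgbl1 among them, where independent lists would share 2.95. A further 10 were lower with SAG and higher with cyclopamine (1.35 for independent lists), including Crabp1 (-2.76 and 0.84). Its cyclopamine call ended without vehicle replicate 1 (adjusted p = 0.0665), vehicle replicate 2 (adjusted p = 0.0677) or cyclopamine replicate 3 (adjusted p = 0.0599). Another 14 were lower with both compounds (1.83 for independent lists), among them Nmur2, Maob and Entpd1, and 0 were higher with both (2.17 for independent lists). Of the 162 probe sets that changed with SAG, 122 had the opposite sign with cyclopamine, and of the 1136 that changed with cyclopamine, 621 had the opposite sign with SAG. Across all probe sets, which are not independent replicates, Pearson's r between the responses was 0.00283 and Spearman's rho 0.171. Unchanged groups simulated against the same vehicle arrays gave a mean r of 0.533 (0.499 to 0.564 over 100 draws). The draws were independent between probe sets, while deviations of a real array can be shared by many probe sets, so that range is likely too narrow. The simulated groups also held no treatment effects, so their changes varied less than the observed ones. Their r is therefore no measure of what shared controls alone would give beside real effects. Leaving out each array in turn gave the observed r a jackknife standard error of 0.195. The covariance was 0.000507 against 0.0354 in the simulation, a difference of -0.0349. No spread was kept for the simulated covariance, so no conclusion on opposed responses across all probe sets is drawn. The 3 vehicle arrays were not split, since they cannot give each response at least 2 of its own, so part of the overlap in the same direction may come from the shared controls.

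**Figure D3:**
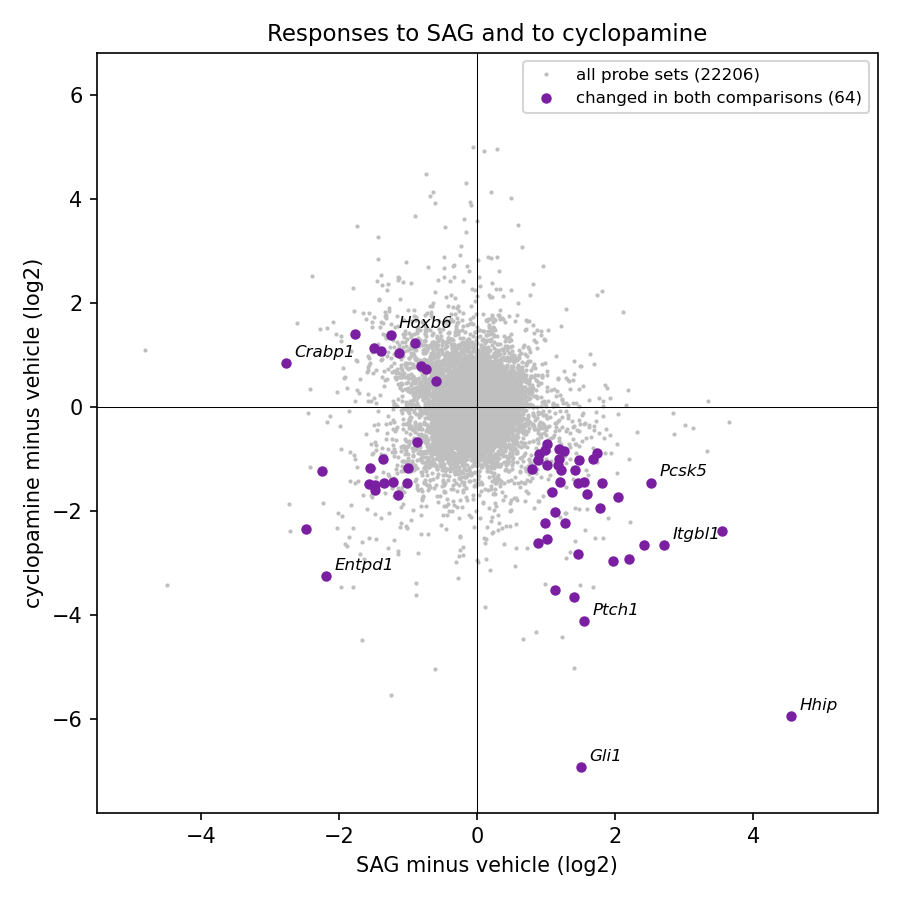
Change with SAG (horizontal axis) and with cyclopamine (vertical axis), each relative to vehicle on the log2 scale, for 22206 probe sets (grey) and the 64 that changed in both comparisons (purple). Hhip lies at 4.55 and -5.95, Gli1 at 1.51 and -6.93, and 40 of the purple points are in the lower right part of the plane.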

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

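The tests of the epithelial and macrophage patterns, the use there of all 16 epithelial genes in place of 12 brighter ones, and a requirement that a value clear its bound by 2 standard errors, were chosen after the results had been seen, while the bounds for the steroid gene pattern were set before. That requirement changed the reading of 3 values: 1.70 against a bound of 2, which would by its bound alone count for a different share of epithelium with SAG, and 0.189 and 0.408 against a bound of 0.5, which would count against their explanations. The value 0.189 lies about 1 standard error (0.305) below its bound, so a requirement of a single standard error would have counted it against carry-over of testis tissue. The standard errors of 0.189 and 0.408 come from the spread between the genes of a list, so they do not measure the spread between arrays. Those of the epithelial ratios come from the number of genes, taken as independent, and do not measure the spread between arrays either.

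In the SAG group, the only group of 4 arrays, 138 genes, lists and array measures were screened for an array far from the other 3 (its gap to the nearest over the whole range), and 9 stood out. Chance gives about 1 in 20, so 9 of 138 is close to the share that chance alone would give. Lists and their own members were both screened, so the items are not independent. SAG replicate 1 stood apart for Ccl6 (0.963; 11.73 against 7.99 to 8.13), Meox2 (0.881; 7.50 against 9.35 to 9.60), Slc7a11 (0.894; 10.10 against 8.94 to 9.06) and Inha (0.8291; 10.19 against 9.18 to 9.35). SAG replicate 2 stood apart for Egln3 (0.920), Kif12 (0.902) and the duct epithelium list (0.867), and SAG replicate 3 for Foxf1 (0.977; 7.11 against 7.29 on each other array) and Id1 (0.864).

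Of 16 duct epithelium genes, 2 fell with SAG and 7 rose with cyclopamine, where 14 changes were positive and 2 negative, and both list calls were lost with an estimated correlation (adjusted p = 0.189 and 0.201). If mesenchyme and muscle alone gained or lost share, the epithelial and endothelial lists would move alike. They moved apart by -1.25 (SE 0.30) with SAG and by 1.95 (SE 0.39) with cyclopamine, which argues against a change of mesenchyme and muscle alone. Mesenchyme gained or lost together with its vessels would also move the lists apart, so that explanation cannot be told apart. With cyclopamine, the SD of the changes of all 16 genes was 3.46 times their median standard error (SE of the ratio 0.63), above the bound of 2 for genes that move alike. This rests on 4 dimmer genes (Ret, Lhx1, Wnt9b and Sall1), since the 12 others gave 2.18 (SE 0.46), too close to the bound. No conclusion on a different share of epithelium with cyclopamine is therefore drawn. With SAG the ratio was 1.70 (SE 0.31) over all 16 genes, too close to the bound, and 1.20 (SE 0.26) over the 12, so a different share of epithelium cannot be told apart from unequal changes of genes. A response of epithelial genes to the treatment stays open for both compounds.

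On SAG replicate 1, genes of steroid synthesis were far above the mean of the other SAG arrays: Cyp17a1 by 4.32 on the log2 scale, Hsd3b1 by 3.84 and Cyp11a1 by 2.42. The median was 1.37 over 8 genes of a Leydig cell list, of which Scarb1 and Fdx1 were bright on all arrays. Over all other arrays the highest value was 4.45 for Cyp17a1 (8.03 on SAG replicate 1) and 7.95 for Hsd3b1 (10.04). For Cyp11a1 it was 8.78 (9.04), so that gene was nearly as high on an array other than SAG replicate 1. Carry-over of testis tissue cannot be told apart. The median of 10 Sertoli cell genes was 0.189 higher (SE 0.30) and that of 10 germ cell genes -0.03, both under the bound of 0.5 set before. That bound was wrong for these genes. Of the Sertoli cell genes, 5 lay above the array median (7.58) on SAG replicate 1, where a small share could be hidden. Among them Wt1 moved by 1.25 and Ptgds by -1.48, and both were higher on another array (10.96 and 14.04). The other 5, with most germ cell genes, lay near the lower end. Amh, an abundant Sertoli cell transcript (0.93 higher, at 4.95), and the germ cell gene Dazl (0.60 higher, at 7.35) lay above all other arrays (at most 4.23 and 7.01), as did Rhox8, Pou5f1 and Stk31 by smaller margins, while Fshr, Dhh and Ddx4 moved by 0.21, 0.19 and -0.26. Carry-over of adrenal tissue cannot be told apart either, with a median of 0.408 (SE 0.17) over 5 adrenal genes outside the Leydig list. Each of these 5 genes was higher on some other array, Mc2r at 9.16 against 7.92 and Mrap at 8.14 against 7.60. No biological explanation was tested.

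With cyclopamine, 8 of 19 chemokine and macrophage activation genes rose and 11 did not pass, but the list was written after the values were seen and holds 5 of the largest rises, and only 3 rose without vehicle replicate 1 or 2 or cyclopamine replicate 1 and 4 without vehicle replicate 3. The median change was 2.42 over the list and 1.57 over the 14 genes outside those 5. A larger share of all leukocytes would raise general leukocyte genes by a like amount. The median of Ptprc, Csf1r, Adgre1, C1qa, C1qb and C1qc was -0.0807 (median SE 0.39), so these genes did not rise with the list. They were chosen after the values were seen, and the leukocyte genes Cd14 and Fcer1g rose. The leukocyte list mean was 1.11 on cyclopamine replicate 1, against -0.13 and 0.06 on the other cyclopamine arrays. A larger share of some leukocytes therefore cannot be told apart. A change of state in resident macrophages under the treatment is a candidate explanation that was not tested further, and Ccl6 was also high on SAG replicate 1.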

How the results depend on the processing

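Leaving out SAG replicate 1 and cyclopamine replicate 2 together was chosen after seeing the data. No named gene or list reversed a called direction under any alternative run. For SAG against vehicle, 162 probe sets became 316 at an adjusted p under 0.10, 1185 at an unadjusted p under 0.05 with at least 1.5-fold, 296 with only the 2 groups in the fit, 313 with array weights, 311 without both arrays that stood apart and 9 with unmoderated variances. Its 7 lists became 0 with an estimated correlation and 2 by the rotation test, and the hedgehog target list (mean 0.84) lost its call with an estimated correlation (adjusted p = 0.189). Centring each array on its median moved the share of higher calls from 61.7% to 72.4%. For cyclopamine against vehicle, 1136 became 1857 and 2416 at those thresholds, 566 with only 2 groups and 568 with unmoderated variances, and 9 lists became 4 with an estimated correlation. For SAG against cyclopamine, 10 lists became 2 with an estimated correlation. Where no construction is named, the cause was not tested.

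Leaving out each array in turn gave 45 to 339 probe sets and 4 to 10 lists for SAG against vehicle, 485 to 1471 and 9 to 10 for cyclopamine against vehicle, and 1843 to 2855 and 9 to 11 for SAG against cyclopamine. The hedgehog target mean ranged from 0.70 to 0.93, from -2.34 to -2.11 and from 3.01 to 3.07, and the correlation of the responses from -0.0849 to 0.169. A lone pair of arrays then remained in some groups, assumed to vary like the others. An array outside the groups compared altered only the shared estimate of spread, not the log2 change of a probe set. Of 172 called results of named genes, those chosen later included, 101 held under all alternatives. Signal near the lower end of the array limits what falls can be measured.

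The replicate number as a block gave 32, 653 and 1613 probe sets for SAG against vehicle, cyclopamine against vehicle and SAG against cyclopamine. SAG replicate 4 has no same-numbered array, so the block removes it from the comparisons. The values gave no sign that the numbers pair the arrays, but so few arrays cannot exclude it. Same-numbered arrays correlated at -0.193 to 0.237 in their deviations from the group means, and other arrays at -0.221 to 0.234. Of the 9 arrays with a same-numbered array in another group, 2 correlated best with their own number.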

Other observations

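The tests of the genes and lists in the first 2 paragraphs were chosen after the values had been seen, so their p-values are not independent evidence. List p-values there were adjusted over the added lists alone, a smaller set than the lists of the main results. Adjustment over all lists together was not tested. Among basement membrane genes, 7 of 18 fell and 0 rose with cyclopamine, and 5 to 8 fell with single arrays left out, with 1 that rose without cyclopamine replicate 2 (mean -0.62, camera adjusted p = 2.33e-05; adjusted p = 0.0532 with an estimated correlation). The collagen IV chains Col4a1 (-1.98 ± 0.18) and Col4a2 (-1.79 ± 0.21) and the laminin chains Lamc3 (-2.87 ± 0.26) and Lama2 (-1.34 ± 0.19) fell, and each call held with any single array left out. The smooth muscle (mean -2.24), endothelium (-0.97) and mesenchyme (-0.68) lists were lower on the same arrays. Of 19 macrophage activation and chemokine genes, 8 rose, of which the lectin gene Lgals3 (3.35 ± 0.29), Gpnmb (2.61 ± 0.44) and Atp6v0d2 passed with any single array left out. The calls of Ccl3, Ccl6, Ccl9, Mmp12 and Trem2 (1.69 ± 0.43) all ended without vehicle replicate 1 or 2 or cyclopamine replicate 1 (adjusted p 0.0550 to 0.163), and that of Trem2 in 8 of the 10 left-out arrays. No list test is given, since the list holds genes that prompted it. Nqo1, a target of the oxidative stress factor NRF2, rose by 1.13, and Cubn, an endocytic receptor of kidney tubules and other absorptive epithelia, by 0.96 from a vehicle mean of 4.72, near the lower end of the signal. The list of acid-secreting epithelial cells did not pass (camera adjusted p = 0.247).

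Hox genes moved in different directions. With cyclopamine, Hoxb8 (2.54 ± 0.31), Hoxb6 (1.39 ± 0.24) and Hoxb2 (1.15 ± 0.19) rose, while 4 of 27 fell, Hoxd13 (-1.92 ± 0.36) among them, whose call ended without vehicle replicate 1 (adjusted p = 0.0629) or cyclopamine replicate 1 (0.0509) or 3 (0.0516). The number that fell was 0 without vehicle replicate 1 or cyclopamine replicate 3, 1 without vehicle replicate 2 or 3 or cyclopamine replicate 1, 2 without SAG replicate 2 or 4 and 6 without cyclopamine replicate 2, where 5 rose. The list mean was -0.45 (camera adjusted p = 0.0446; adjusted p = 0.184 with an estimated correlation), and that call ended without vehicle replicate 1 (0.0762) or 2 (0.116), SAG replicate 2 (0.0580) or 4 (0.0540), or cyclopamine replicate 1 (0.0769). The Hox call with cyclopamine lies near the threshold and may not hold when adjusted over all lists together. With SAG, Hoxb9 (-1.82 ± 0.32) and Hoxb6 (-1.25 ± 0.23) fell, with calls that ended in 5 and 7 of the 10 left-out arrays, and the list mean was -0.36 (camera adjusted p = 0.000764; adjusted p = 0.0840 with an estimated correlation). Aldh1a3, a retinoic acid-producing enzyme, rose with cyclopamine (1.76 ± 0.31) and did not pass with SAG (-0.66 ± 0.29, limma adjusted p = 0.442). The retinoic acid list did not pass in either comparison (camera adjusted p = 0.0616 for SAG and 0.572 for cyclopamine). Among genes with opposite changes were Gpc3, a glypican that binds hedgehog ligands (1.22 with SAG and -1.22 with cyclopamine), the hyaluronan synthase gene Has2 (1.27 and -2.23), Tgfb3 (1.01 and -1.13) and Timp3 (1.46 and -1.46). The SAG call of Has2 ended without vehicle replicate 1 (adjusted p = 0.0997), 2 (0.125) or 3 (0.0691) or SAG replicate 2 (0.0648) or 3 (0.0659), and that of Tgfb3 without vehicle replicate 2 (0.0769) or 3 (0.0549). Genes lower with both compounds included Galnt16 (-1.48 and -1.60) and the glutamate receptor gene Gria1 (-1.21 and -1.44). Their SAG calls ended without vehicle replicate 2 (adjusted p = 0.0509 and 0.141), and that of Gria1 in 6 of the 10 left-out arrays.

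Other splits of the same arrays into groups of the same sizes were counted, as set before the data were examined. For SAG against vehicle, 1 of 35 splits, the real one, gave as many as 162 probe sets, a share under 0.05, and the highest of the others gave 17. Splits that mix treated and vehicle arrays hold any treatment effect as spread within groups, which can lower their counts. The splits therefore do not exclude chance as a source of that count. For SAG against cyclopamine it was again 1 of 35, with 2518 against at most 28. For cyclopamine against vehicle, 10 splits are too few for a share under 0.05; the real split gave 1136 and the highest other 3.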
